A study of Streptomyces bingchenggensis with 12 samples.

How the data were processed

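The series measured gene expression by RNA-seq in mycelia of Streptomyces bingchenggensis strains BC-101-4 and BC04 at 6 times, with 1 sample per strain and time. Per the labels' protocols, mycelia were frozen in liquid nitrogen, RNA was taken up in Trizol and libraries were made with Illumina protocols. Per the submitters' processing notes, reads were aligned with Bowtie2 2.2.3. The counting tool, genome build, annotation and filters are not given in the sources used here.

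Each deposited file holds a locus tag, 3 numbered columns of values, strand, start, end and length for 9689 genes, with the same genes in the same order. The header names no unit. The deposited values behave as RPKM made by the authors, and RPKM and FPKM cannot be told apart from them. In each column, value times length sums to nearly the total that this unit implies, and low values times coding length are whole multiples of a single step. The step gives the depth: 3.77 to 7.98 M reads per column. Of values worth under 100 reads, 83.0% were whole within 0.05 reads at the listed coding length. For 1252 genes another length could be found at which the values were whole, and for 3068 genes the length could not be determined. The authors' gene lengths may thus differ from the listed ones, which would affect the RPKM of a gene in every sample alike. With the other lengths, however, the share of reads left outside the listed genes turned negative in most columns (mean -2.17% in BC-101-4 at 72 h). At the listed lengths it was 1.16% to 6.86%. The other lengths are thus uncertain too. All coding lengths were multiples of 3. The values are not counts, so no count-based test was run.

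Nothing says whether the 3 columns of a file are separate cultures. They differed by more than sampling noise (chi-square per degree of freedom of 1.85 to 24.7 over 36 column pairs, Pearson r of log2 values 0.983 to 0.992). They were averaged on the log2 scale into 1 value per sample, so that the main fits hold 12 samples and no group has replicates. SDs and SEs over columns, and tests with columns as libraries, describe only the spread between columns. Counting error limits a gene at the lowest depth to steps of 0.266 RPKM per read and kb.

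Tests were run on log2(RPKM + 1), without further scaling, after leaving out genes with a mean RPKM under 1, which kept 8676 genes. A fold change on this scale understates the change of low genes. limma 3.58.1 in R 4.3.3 (eBayes with trend) was used with Benjamini-Hochberg adjustment and a threshold of 0.05. The strain difference was fitted with time as a 6-level block (5 residual degrees of freedom), the change over time with strain as a term, and the phase interaction with 4 residual degrees of freedom. In the first 2 fits the residual is the strain by time difference plus the noise of single samples. Their p-values thus ask for a difference kept over the times or a change shared by the strains. They do not measure the spread between cultures. Per-time ratios used a prior of 2 reads and carry no test. Runs are 5 or more neighbours called in the same direction with at most 1 uncalled gene between members. Runs over time also required a change of at least 4-fold, and runs at single times a difference of at least 2-fold in the test over columns. The strain runs and the runs over time were compared with 1000 shuffles of gene order. A silent gene is under 0.1 RPKM in all 18 columns of a strain and at 5 or more in all 18 of the other. The regions' mean strain differences over the 6 times were tested with an exact sign-flip permutation test (two-sided), over 49 regions. It is reported for the loci of long genes only, since the runs were picked from calls on the same 6 times. Regions include genes left out of the fits. Where genes overlap or share sequence, how the authors assigned reads is not known, and the values of such genes are uncertain.

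These designs, and the rule that names genes (the largest rises and falls past the test with the same direction in every pair, limited to 2 each way because the files hold no product text), were set before the data were examined. For the same reason, the planned lists of genes by function and a planned analysis of the milbemycin genes were left out. Groups by position (bins of 1 Mb) and coding length, runs over time, runs per time, loci of genes of 10 kb or more joined within 50 kb, and tests over columns (24 residual degrees of freedom) were chosen after seeing the data. The groups were tested with camera in limma at a preset correlation of 0.01, with fry and with an estimated correlation. The alternatives were other scalings, filters, pseudocounts, time terms, phase boundaries and run settings, and leaving out samples. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

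The fits were tested on simulated data with 200 changed genes among 8676. For the strain difference, 98 of 100 genes changed 4-fold and 87 of 100 changed 2-fold were recovered, with 5 false calls. For 192 h against 18 h, 83 of 100 and 34 of 100 were recovered, and for the phase interaction 82 of 100 and 10 of 100. Of 20 planted runs of 6 genes changed 8-fold, 20 were found. The strain runs in the data were shallower, with mean log2 differences of -0.97 to -2.37, so this recovery does not cover them. The simulated noise was independent between genes and samples and held no shift of a whole library.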

Results

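RNA was sequenced from mycelia of 2 strains of Streptomyces bingchenggensis, a filamentous soil bacterium with a linear chromosome, at 6 times of culture: 18 h, then 48 and 72 h, 96 h, and late, at 144 and 192 h. The labels call BC-101-4 the wild type and BC04 a high-yielding strain, and they give 1 sample per strain and time, 12 samples in all. Each sample's file holds 3 numbered columns of RPKM (reads per kilobase of gene, scaled to the reads of the library) for the same 9689 genes, and nothing says whether the columns are separate cultures. The low values place the depth at 3.77 to 7.98 M reads per column, so that 1 read in a gene of 1 kb is worth 0.125 to 0.266 RPKM. Values below are means of the 3 columns with the SD between columns (n = 3), and any test over columns measures only the spread between columns, which may be technical. Genes are named by locus tag and regions by position, in the coordinates of the files, whose genome build is not given in the sources used here. The files do not pair the locus tags with gene names or products.

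The libraries divided first into 18 h and later times. From 72 h on, each sample correlated best with another time of its own strain. BC-101-4 at 144 h, for example, stood at r of 0.986 with its own 192 h and 0.946 with BC04 at 144 h. The 18 h samples stood apart: the log2 profiles of 18 h correlated with those of later times at Pearson r of 0.679 to 0.747 across genes, against 0.915 to 0.992 between later times of a strain and 0.946 to 0.973 between the strains at the same time. The leading principal component, which held 66.0% of the variance, separated 18 h from the rest. The next component (12.8%) ordered the later samples of each strain by time, and the third (9.08%) set BC04 apart from BC-101-4 after 18 h.

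The first comparison asks how expression changed from 18 h in both strains alike. The rising run with the most genes was a stretch of 49 listed genes at 8175043 to 8231469, of which 46 rose at least 4-fold by 192 h. Its mean log2 level went from 1.86 ± 0.10 at 18 h to 10.03 ± 0.03 at 96 h in BC-101-4 and from 2.18 ± 0.08 to 10.08 ± 0.02 in BC04, and it lay between 9.48 and 10.25 at all times from 48 h on. This stretch of 56.4 kb took 0.0573% of the reads at 18 h and 12.1% at 192 h in BC-101-4, and 0.0661% and 15.3% in BC04. A region at 1025965 to 1087301 rose alongside it, with all 11 of its genes at least 4-fold higher at 192 h. Its mean log2 level went from 1.24 ± 0.10 to 8.95 ± 0.11 by 48 h in BC-101-4 and from 1.33 ± 0.12 to 8.94 ± 0.04 in BC04.

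Other regions rose and then declined, or were highest at the start. In the region at 560309 to 595323, 22 of 26 genes were at least 4-fold higher at 192 h than at 18 h, but its level was highest at 72 h, at 7.56 ± 0.07 in BC-101-4 and 6.88 ± 0.47 in BC04. The 14 genes at 7504169 to 7510699 were among the most abundant at 18 h, with 2.17% of the reads in BC-101-4 and 2.96% in BC04, and all 14 fell at least 4-fold, to 0.495% and 0.324% at 192 h. All 13 genes at 8601557 to 8617084 also fell, from a mean log2 level of 5.83 ± 0.29 to 1.71 ± 0.05 in BC-101-4 and from 5.44 ± 0.09 to 1.27 ± 0.06 in BC04. Runs over time were built from genes past the test at 192 h with a change of at least 4-fold. There were 13 runs of 5 or more rising neighbours, holding 147 such genes, and 35 runs of falling ones, holding 237. Shuffling the gene order 1000 times gave at most 8 such runs (one-sided permutation p = 0.001, the smallest it can give).

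Among single genes, the largest rises past the test at 192 h were those of SBI_03481 (4526284 to 4526682, minus strand) and SBI_06851 (8203275 to 8203733, minus strand). SBI_03481 went from 1.65 ± 1.5 RPKM at 18 h to 77860 ± 4499 at 192 h in BC-101-4 and from 6.25 ± 3.13 to 101500 ± 6092 in BC04 (log2 change 14.46, SE 0.46, adjusted p = 1.35e-07, limma). SBI_06851 rose by 12.29 (SE 0.19, adjusted p = 6.02e-09). The largest falls were those of SBI_05165 (6359901 to 6361382) and SBI_05167 (6362293 to 6363270), both on the minus strand. SBI_05165 went from 1268 ± 254.3 RPKM to 2.07 ± 0.38 in BC-101-4 and from 1141 ± 57.4 to 0.833 ± 0.401 in BC04 (log2 change -8.99, SE 0.24, adjusted p = 3.90e-08), and SBI_05167 changed by -8.33 (SE 0.21, adjusted p = 3.52e-08).

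In numbers of genes, 1703 were higher and 3533 lower at 48 h than at 18 h at an adjusted p under 0.05, of 8676 tested. The counts were 2091 and 3256 at 72 h, 1938 and 3565 at 96 h, 1919 and 3512 at 144 h, and 1839 and 3623 at 192 h. The excess of falling genes depended on the scaling. After quantile normalization it was smaller but remained at every later time, with 1999 higher and 2851 lower at 48 h and 2302 and 2933 at 192 h. The median gene moved by -0.41 on the log2 scale from 18 h to 192 h in the values as deposited and by 0.12 after upper quartile scaling, when 2392 genes were higher and 2439 lower at 48 h, 2665 and 2545 at 72 h, 2766 and 2610 at 96 h, 2915 and 2405 at 144 h, and 2875 and 2460 at 192 h.

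**Figure D1:**
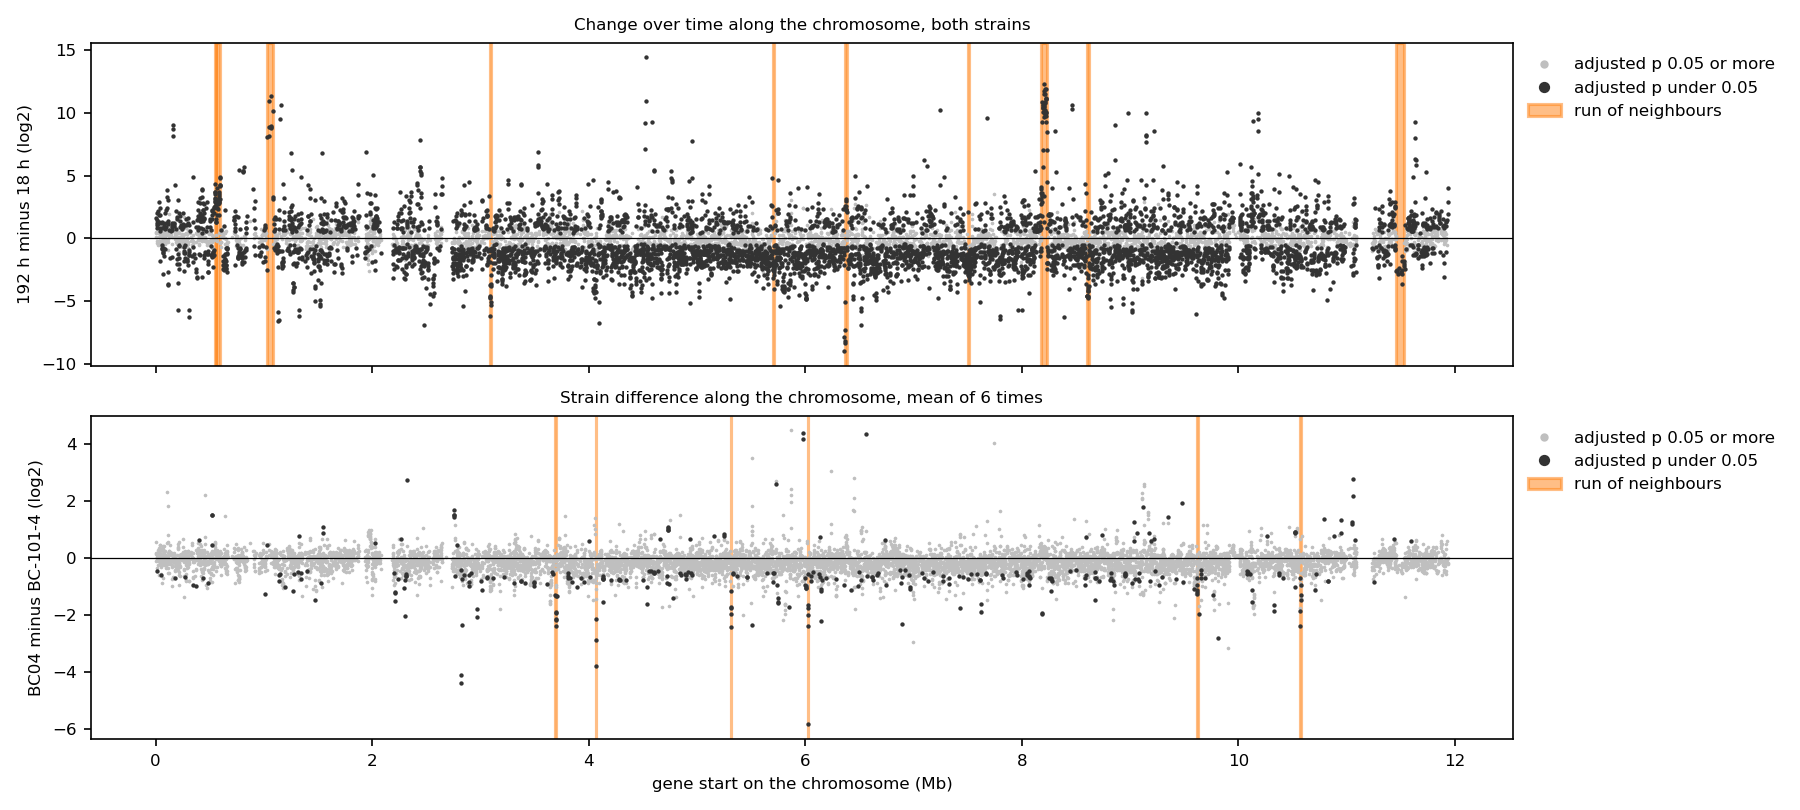
Each point is a gene at its start on the chromosome (Mb), with the log2 change from 18 h to 192 h over both strains (upper panel) or the mean BC04 minus BC-101-4 log2 difference over the 6 times (lower panel), dark where the adjusted p is under 0.05 (limma). Orange bands mark the 5 longest rising and 5 longest falling runs over time, and the 5 strain runs with the 3-gene run that holds the silent gene; the dense column of high points near 8.2 Mb is the stretch at 8175043 to 8231469.

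Along the chromosome, the median change over time varied between bins. In the values as deposited, the median gene of the bin from 1 to 2 Mb moved by 0.22 from 18 h to 192 h and that of the bin from 7 to 8 Mb by -0.82. Of 15 groups tested by position or coding length, 8 stood out from the other genes at a preset correlation of 0.01 (camera in limma): upward, the bins 0 to 1 Mb, 1 to 2 Mb and 11 to 12 Mb, the 14 kept genes with a coding length of 10 kb or more and the 736 kept genes under 300 bp, and downward, the bins 5 to 6, 6 to 7 and 7 to 8 Mb. None of these calls held with an estimated correlation, where the lowest adjusted p = 0.378, for the long genes. Between the strains, the bins 0 to 1 Mb, 1 to 2 Mb and 11 to 12 Mb were higher in BC04 relative to the other genes at the preset correlation (adjusted p = 0.00739, 0.00739 and 0.00194), with medians of -0.03, -0.04 and -0.06. With an estimated correlation none held (adjusted p = 0.929 for each), and without 96 h the preset called 6 groups.

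The next comparison asks which genes differed between BC04 and BC-101-4 throughout the time course. Genes lower in BC04 were found in 5 runs of neighbours, at 3691602 to 3698330, 5309065 to 5312659, 6021632 to 6026082, 9617183 to 9622401 and 10571611 to 10578965, and no run of 5 or more was higher. The deepest was the 6-gene run at 6021632 to 6026082. Its mean log2 level was 6.72 ± 0.11 in BC-101-4 and 5.04 ± 0.06 in BC04 at 18 h, and 6.84 ± 0.06 and 3.85 ± 0.20 at 144 h. The mean differences of the 5 runs over the 6 times, in the order given first, were -1.66 ± 0.73, -1.80 ± 0.90, -2.37 ± 0.48, -0.97 ± 0.25 and -1.49 ± 0.70 (SD, n = 6 times). The difference was negative at each of the 6 times in all 5 runs. At 18 h it was small at 5309065 to 5312659 (-0.25, SE 0.10) and at 10571611 to 10578965 (-0.21, SE 0.14). Because the runs were picked from calls on these same 6 times, no p-value is given for their means. Shuffling the gene order 1000 times gave at most 1 run (one-sided permutation p = 0.001, the smallest it can give). Random order also separates neighbours that vary together for any reason. The test shows only that called genes lay side by side, as they also did over time, and not that the blocks are particular to the strains. Leaving out 96 h, 144 h or 192 h left 0 runs, leaving out 72 h left 1, leaving out 18 h gave 39, and leaving the 20 largest genes out of the library sizes left 2.

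Within the deepest run lies SBI_04846 (6024054 to 6024479, minus strand), the gene with the largest fall in BC04. It averaged 2417 ± 962.5 RPKM in BC-101-4 and 43.6 ± 25.5 in BC04 (SD, n = 6 times; log2 difference -5.83, SE 0.48, adjusted p = 0.00138, limma). The next was SBI_02067 (2822236 to 2823648, plus strand), with 3746 ± 50 RPKM in BC-101-4 and 177.3 ± 4.45 in BC04 at 48 h, its time of highest level in both strains (log2 difference over all times -4.39, SE 0.12, adjusted p = 2.70e-06). The largest rises among genes higher at all 6 times were those of SBI_04806 (5976007 to 5976798, minus strand) and SBI_09281 (11056031 to 11057347, plus strand). At 96 h, SBI_04806 stood at 600.3 ± 169.1 RPKM in BC04 and 1.26 ± 0.66 in BC-101-4, and SBI_09281 at 653.1 ± 74.2 and 27.7 ± 0.964, the largest gap of the 6 times for both. At 18 h they were nearly alike in the strains, SBI_04806 at 1.08 ± 0.094 and 0.662 ± 0.289 RPKM and SBI_09281 at 6.43 ± 0.096 and 6.17 ± 0.425. At 72 h the BC04 columns spread widely, at 49.5 ± 54.6 RPKM for SBI_04806 and 120.2 ± 96.1 for SBI_09281. Both were close to the threshold, with log2 differences of 4.16 (SE 0.84, adjusted p = 0.0432) and 2.77 (SE 0.52, adjusted p = 0.0373). Neither passed when 48, 72, 96, 144 or 192 h was left out, and SBI_04806 did not with upper quartile scaling (adjusted p = 0.0502).

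In all, 58 genes were higher and 279 lower in BC04 at an adjusted p under 0.05, and 324 of these 337 differed the same way at all 6 times. The median gene differed by 0.02 at 18 h and by -0.32 at 192 h, and by -0.15 on average over the times. Relative to it, the mean differences of the runs, in the order given first, were -1.51, -1.65, -2.22, -0.82 and -1.34. The split into higher and lower genes depended on this shift: it was 100 and 122 after quantile normalization, 84 and 87 after upper quartile scaling, 57 and 163 with the 20 largest genes left out of the library sizes, and 101 and 108 with every column set to the same median. The count itself depended on single times: it was 1366 without 18 h, 43 without 72 h, 19 without 96 h, 22 without 144 h and 14 without 192 h.

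A single gene, SBI_03115 (4067578 to 4068849, minus strand), met the rule for a gene silent in a strain, and it was silent in BC04; it was chosen for naming after its values were seen. It stood between 7.69 and 19.7 RPKM in the BC-101-4 samples, which corresponds to 1814 reads over 18 columns, and had 0 reads in all 18 BC04 columns. Its neighbour at 4067303 to 4067560 also had 0 reads in BC04 against 196 in BC-101-4, and the next gene, at 4066466 to 4067299, averaged 1.1 RPKM in BC04 and 10.1 in BC-101-4. The 3 genes form a run of called neighbours whose mean log2 level was 3.94 ± 0.26 in BC-101-4 and 0.08 ± 0.08 in BC04 at 18 h. No gene was silent in BC-101-4 alone by the same rule.

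Single times brought larger differences between the strains than their average. The 5 genes at 5864536 to 5872603 were alike at 18 and 48 h and then differed: their mean log2 level was 7.67 ± 0.08 in BC04 and 4.23 ± 0.03 in BC-101-4 at 72 h, and the BC04 minus BC-101-4 difference was 3.87 (SE 0.05) at 96 h, 4.01 (SE 0.09) at 144 h and 3.39 (SE 0.11) at 192 h. Their share of the reads at 96 h was 0.851% in BC04 and 0.0142% in BC-101-4. The 14 genes at 3639423 to 3654288 did the opposite. In BC-101-4 they stood at 1.40 ± 0.09 at 96 h, 5.67 ± 0.47 at 144 h and 3.58 ± 0.37 at 192 h, while in BC04 they stayed between 1.47 and 1.63 throughout.

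At 18 h the strains differed in regions that differed less, or not, later. The 13 genes at 3086162 to 3103909 were lower in BC04 by 3.81 (difference -3.81, SE 0.64) at 18 h, and the difference lay between -0.37 and 0.10 from 48 h on. The 25 genes at 1961988 to 1994184 were higher in BC04 at 18 h, with a difference of 3.58 (SE 1.2), and the BC04 columns of that time spread from 3.25 to 7.25, so that the size of this difference is poorly fixed. The 10 genes at 3941946 to 3951473 were lower in BC04 at 18 h (difference -2.53, SE 0.19). Their difference was -0.73 (SE 0.08) at 96 h and turned to 0.52 (SE 0.06) at 144 h. At 48 h the 8 genes at 1166321 to 1176040 were lower in BC04 (-2.74, SE 0.13), and at 72 h the 13 genes at 9587171 to 9603592 were (-2.40, SE 0.21).

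**Figure D2:**
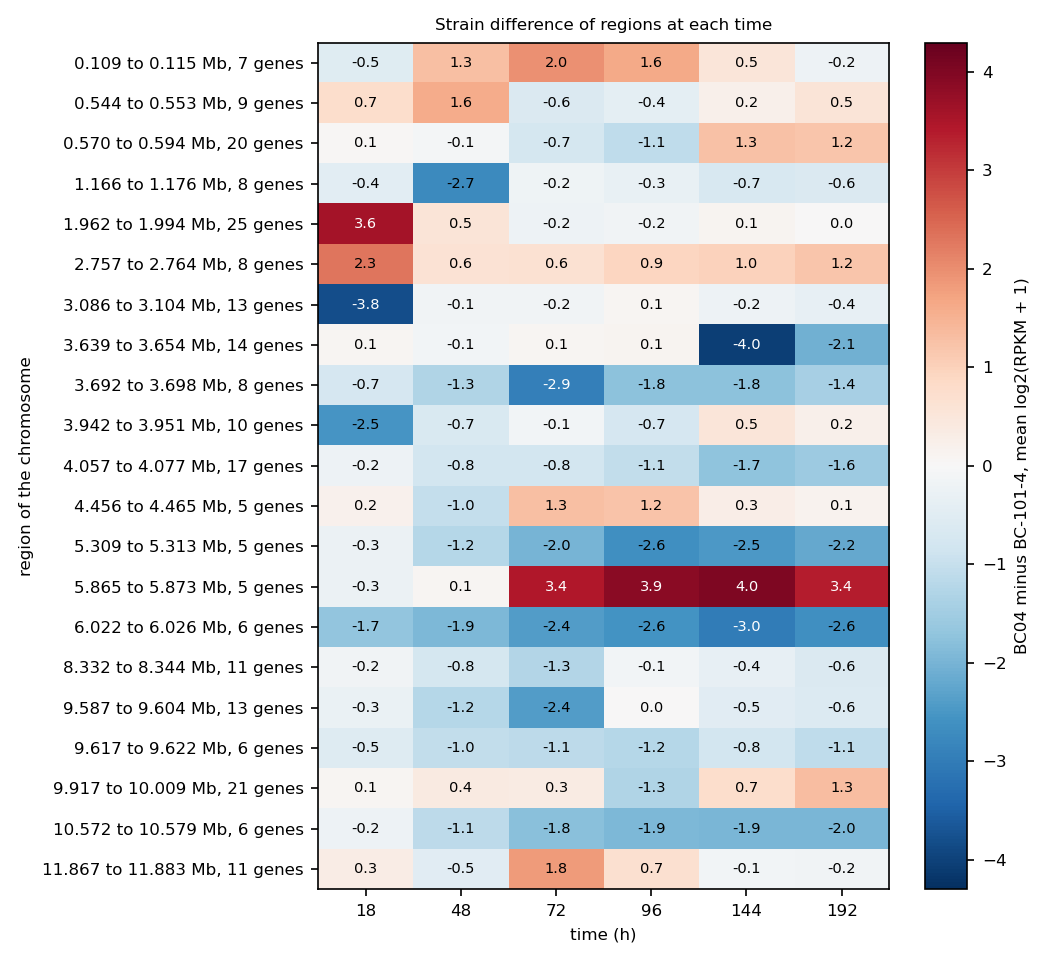
Rows are 21 regions of neighbouring genes and columns the 6 times (h), and colour and number give the BC04 minus BC-101-4 difference in mean log2(RPKM + 1), each from 3 columns per sample. Regions of a single colour across a row, such as 6.022 to 6.026 Mb, differ throughout, while 1.962 to 1.994 Mb and 3.639 to 3.654 Mb differ at 18 h and from 144 h on, in that order.

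Counted over all genes, 56 were at least 4-fold higher and 54 lower in BC04 at 18 h with an RPKM of at least 10 in either strain, a count without a test. The numbers were 35 and 59 at 48 h, 46 and 106 at 72 h, 61 and 74 at 96 h, 43 and 208 at 144 h, and 41 and 151 at 192 h. After quantile normalization they were 70 and 166 at 144 h and 71 and 95 at 192 h. With the 3 columns of each sample taken as libraries, a limma test called 277 genes higher and 180 lower by at least 2-fold at 18 h, and 197 higher and 1065 lower at 192 h. This test used the values as deposited, where the median gene differed by -0.32 at 192 h. It was not repeated after another scaling, so the part of the shift in these counts is not known. The strain differences of 72, 96, 144 and 192 h resembled each other across genes (Pearson r of 0.482 to 0.796), and those of 18 h resembled none of these (r of -0.01 to 0.10); genes are not independent replicates.

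A further comparison asks whether the strain difference changed between an early phase (18, 48 and 72 h) and a late phase (96, 144 and 192 h). In the 12-sample fit, limma called 0 genes, and 1277 had an unadjusted p under 0.05. The count moved with the boundary: with 72 h moved to the late phase 106 genes were called, and with 96 h moved to the early phase 2. A trend over log2 hours in place of the phases called 201, and leaving out 72 h gave 33. The difference at 5864536 to 5872603 set in at 72 h, within the early phase, and that at 3639423 to 3654288 at 144 h, within the late phase.

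The strains can also be compared at loci of very long genes, a group chosen after the files were seen. In streptomycetes, genes with a coding length of 10 kb or more mostly encode modular polyketide synthases or non-ribosomal peptide synthetases, which build secondary metabolites; the files do not say what these genes encode. There were 24 such genes at 11 loci, and several were nearly silent. At 848197 to 943290, for example, 4 of them stood between 0.27 and 0.73 in mean log2 level at all times in both strains. Strongly expressed from 48 h on were 3 adjacent genes at 1025965 to 1081234, a gene at 1146684 to 1159715 and a gene at 160217 to 170530. Adjacent here means next to each other among the genes of 10 kb or more, and shorter genes may lie between them. The 3 adjacent genes took 4.74% of the reads at 192 h in BC-101-4 and 6.55% in BC04, and the gene at 1146684 to 1159715 took 1.89% and 2.49%.

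Among the 3 adjacent genes the strain difference was uneven. The gene at 1025965 to 1043364 stood at 1264 ± 45.3 RPKM in BC-101-4 and 2200 ± 57.5 in BC04 at 192 h, a log2 difference of 0.80 (SE 0.04). It was higher in BC04 at all 6 times, though at 18 h by 0.43 with an SE of 0.25. No p-value is given for it, since it was picked after its values were seen. The gene at 1063754 to 1081234 stood at 772.8 ± 30.3 and 775.0 ± 37.7 RPKM, a log2 difference of 0.00 (SE 0.05), at a time when the median gene differed by -0.32. The middle gene, at 1045885 to 1060944, went both ways, with a log2 difference of -0.58 (SE 0.12) at 48 h, 0.50 (SE 0.06) at 72 h and 0.02 (SE 0.09) at 192 h. The gene at 160217 to 170530 was lower in BC04 at 48 h, with a mean log2 level of 7.03 ± 0.02 against 8.73 ± 0.08 in BC-101-4, and not at 72 h, with 9.62 ± 0.12 against 9.25 ± 0.05. The 4 long genes at 9918279 to 9993800 peaked at 48 h in both strains, at 6.97 in BC-101-4 and 7.33 in BC04. As mean differences over the 6 times, none of the 11 loci passed the exact sign-flip permutation test, where the lowest unadjusted p = 0.0625 (adjusted p = 0.161). Even the smallest p that this test can give, 0.03125, had an adjusted p = 0.118 over the 49 regions. The absence of a call thus says little. Relative to the median gene, 4 of the 11 loci had the smallest possible exact permutation p, 0.03125 (unadjusted), at 848197, 1380629, 2645076 and 10915566. Their genes stood at 2.40 RPKM or less, where adding 1 before the log shrinks differences. Without the median taken off, their mean differences were only 0.03 to 0.11. The result thus comes mostly from the median gene, which was lower in BC04 from 48 h on, and says little of these loci.

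**Figure D3:**
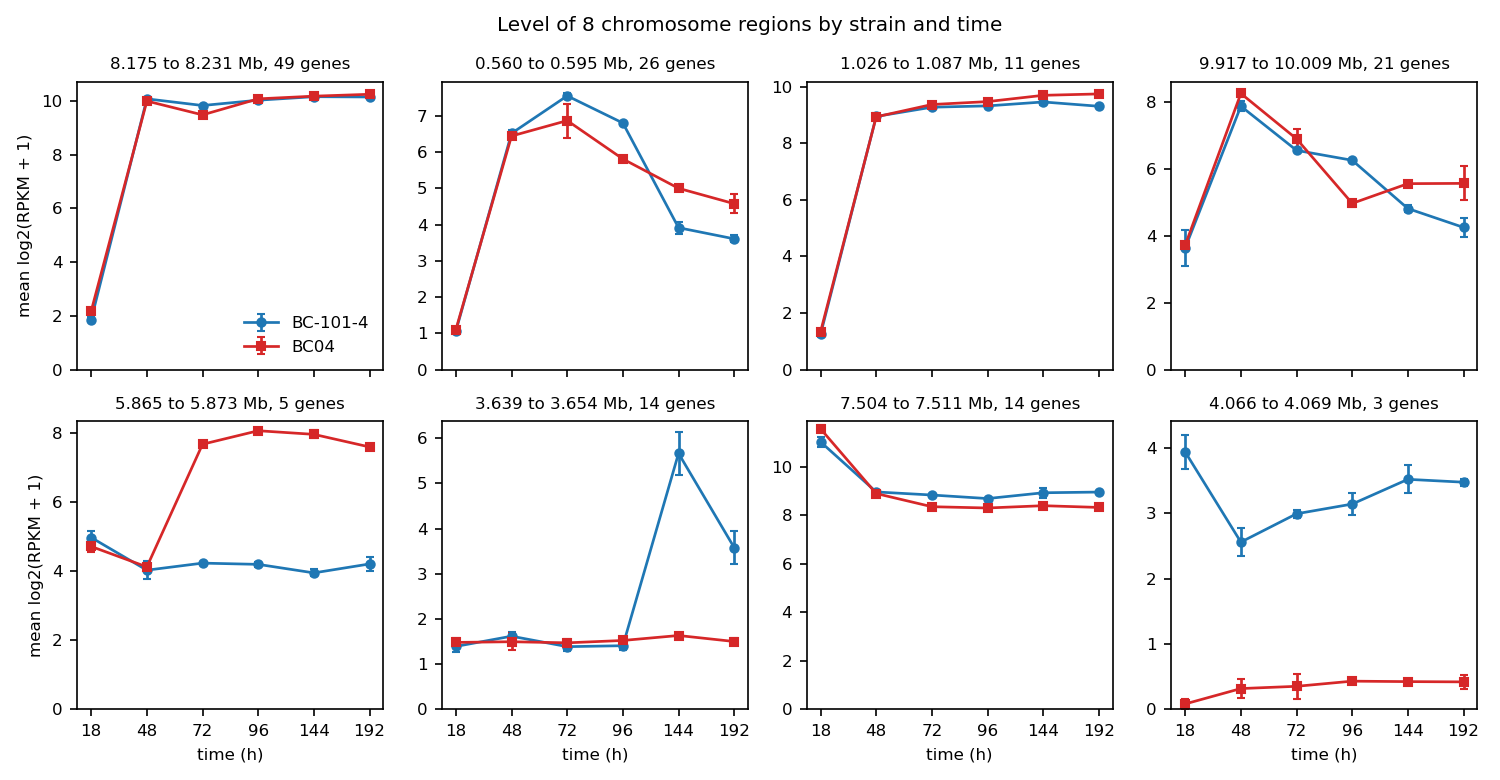
Mean log2(RPKM + 1) of the genes in 8 regions against time (h, evenly spaced), for BC-101-4 (blue circles) and BC04 (red squares); bars are the SD between 3 columns. The region at 5.865 to 5.873 Mb separates the strains from 72 h, that at 3.639 to 3.654 Mb at 144 and 192 h, and the 3-gene run at 4.066 to 4.069 Mb at all 6 times.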

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

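All tests of explanations in this part were chosen after the results were seen, except the exchanges of labels. The test over genes grouped by level replaced a test of the split after setting every column to the same median, which was dropped after its value was seen because the centring nearly fixes it. No sample could be tested for lying far from its group, since each group holds 1 sample.

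The strain difference itself differed between times for many genes, by a test of that change. With columns as libraries, 5805 of 8676 genes passed a limma F test of strain by time, and 230 of them were at least 2-fold higher in BC04 at some time and at least 2-fold lower at another. Of the runs found at single times, 3 stretches had a mean difference above 1 at some time and below -1 at another; other runs turned direction by less. In the region at 9916986 to 10009213, which holds 4 genes of 10 kb or more, all 21 genes passed; its difference was -1.29 (SE 0.07) at 96 h and 1.32 (SE 0.34) at 192 h. At 569737 to 594278 all 20 genes passed, with -1.08 (SE 0.07) at 96 h and 1.27 (SE 0.12) at 144 h, and at 4455798 to 4464861 all 5 passed, with -1.02 (SE 0.03) at 48 h and 1.29 (SE 0.13) at 72 h. The 3 stretches were picked for turning direction in the same columns, so that their genes passing is nearly fixed by that choice. These tests measure the spread between columns only.

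More genes were lower than higher in BC04, and the median gene's difference grew to -0.32 at 192 h. A few dominant genes do not account for it alone: with the 20 largest genes left out of the library sizes the median was still -0.197 at 192 h, although their share of the reads was 27.7% in BC04 and 21.1% in BC-101-4. A difference in depth does not account for it either, since the time with the largest depth ratio, 18 h, had a median difference of 0.0203. A single scaling factor per library stays open: with genes split by level into 5 equal groups, the medians of the 3 upper groups at 192 h differed by 0.117, neither alike within 0.1 nor apart by 0.2. A lower level of many genes in late BC04 is the biological alternative and was not tested apart from it.

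The 2 neighbouring genes at 4067303 to 4068849 had no reads in BC04. Depth cannot account for this, since 2280 reads were expected there at the BC-101-4 level of each time and a count of 0 allows up to 3. Missing or changed sequence in BC04, and transcription shut off with the sequence kept, cannot be told apart with RNA alone. Of the next genes on either side, 0 of 2 were at 0 in all 18 BC04 columns, which a loss of these 2 genes alone does not forbid. SBI_03115 was the 1 gene at 5 RPKM or more in every BC-101-4 column and at 0 in every BC04 column.

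Among the 3 adjacent long genes at 1025965 to 1081234 the strain difference was uneven. A scaling factor cannot produce this, since the ratio of the gene at 1025965 to that at 1063754 within a library was higher in BC04 by 0.796 (log2, SE 0.03) at 192 h, and such a factor leaves this ratio as it is. This was the largest value, and at the earlier times the ratio was higher by 0.20 (48 h) to 0.38 (72 h). No p-value is given, as the genes were picked for being apart. Reads shared between the 3 genes, as paralogs may share sequence, stay open and cannot be told apart from a change in the genes themselves: at 2 of 6 times the ratio differed by more than 2 SE while the sum of the 3 genes did not, at 48 h (sum 0.06, SE 0.10) and at 18 h, where the sum's spread was wide (0.49, SE 0.28). At 192 h the sum was higher by 0.45 (SE 0.05). Reads shared alike in both strains would leave the ratio unchanged under an even rise of the 3 genes. Only reads shared unequally between the strains would then move it, which was not tested. A difference between the strains in transcription of these genes stays open, untested.

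For the strain difference, 337 genes were called with the real labels, and the highest of the other 31 exchanges of labels within times called 2. Thus 1 of 32 reached the real count, which argues against chance only if the 6 times are independent pairs. The strain differences of 72 h to 192 h correlated at r of 0.482 to 0.796 across genes. Exchanging single times breaks that structure, so the counts of the other exchanges are too low if the times of a strain share a culture. Leaving out 192 h alone already brought the count to 14. The exchanges used the values as deposited, where the median gene differed by -0.15 on average, and an exchange turns that shift too. They therefore cannot tell a shift of scale from changes of single genes. For the phase interaction, the 10 splits of the 6 times are too few for a share under 0.05; the real split called 0 genes, a count reached by 10 of 10, and the highest other called 4.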

How the results depend on the processing

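With no replicates, the counts rest on single pairs of samples, and depth leaves genes near 1 RPKM with few reads. The upper quartile and same-median scalings apply 1 factor per column, so that the split moves with the reference; the cause of the other changes was not tested. The same-median scaling, the averaging of linear values, the columns as libraries, the scalings of runs other than quantile normalization, and all settings of the position and length groups were added after seeing the data. The planned count-based tools were not run because the values are not counts, and the gene list and milbemycin alternatives were not run because the files hold no product text.

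The strain difference, 337 genes, became 222 after quantile normalization, 171 after upper quartile scaling, 220 with the 20 largest genes left out, 209 with every column set to the same median, 22 without a time term, 103 at 2-fold or more and 4501 with 36 columns as libraries. Leaving out a time gave 14 to 1366; the 14 without 192 h and the 43 without 72 h shared 14 and 42 genes with the 337. Of the 222 and 171, 171 and 137 were shared. The 5 runs became 3 after upper quartile scaling, 2 with the 20 largest genes left out, 28 with runs of 3 and 3 with no gap, and 0 to 39 with a time left out.

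Each count of changes from 18 h stayed within 1.5 times, but upper quartile scaling turned the majority upward at 72 h (5210 genes), 96 h (5376), 144 h (5320) and 192 h (5335). The phase interaction gave 106 genes with 18 and 48 h as early, 2 with 18 to 96 h as early, 201 with log2 hours, and 0 to 33 with a time left out. The counts per time at 2-fold in place of 4-fold were 338, 475, 490, 513, 962 and 979 from 18 h to 192 h. The majority turned at 18 h with a minimum of 2 RPKM (117 genes) and at 96 h after quantile normalization (135). The position and length groups called between strains, 3, became 5 with the stricter filter, 0 with an estimated correlation and 3 to 6 with a time left out. Those called over time, 8, became 0 with an estimated correlation. The silent genes became 2 with a level of 1 in the other strain. The other 152 alternative counts stayed within 1.5 times with the same majority. Of the 8 named genes, SBI_04806 and SBI_09281 lost the call in 13 alternatives with the direction kept, and 135 others kept direction and call. The mean strain differences of the 49 regions were recomputed under other scalings and a pseudocount of 0.1, settings added after seeing the data. Of these values, 18 moved by more than the region's SD over the times and 227 did not.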

Other observations

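The test of a hypothesis in this part was chosen after the result was seen. Some regions differed between the strains without being described above. The 8 genes at 2757288 to 2764077 were higher in BC04 at all 6 times, by 2.31 (SE 0.38) at 18 h and by 0.61 (SE 0.08) at 48 h to 1.20 (SE 0.10) at 192 h. Around the 3-gene run that holds the 2 genes without reads in BC04, the other 14 genes at 4057328 to 4077284 were higher in BC04 at 18 h, with a mean difference of 0.55 (SE 0.11), and lower from 48 h on, with -0.47 (SE 0.03) at 48 h and -1.44 (SE 0.09) at 144 h. The 7 genes at 109071 to 114971 were higher in BC04 from 48 h to 144 h (0.51, SE 0.12), with 1.98 (SE 0.23) at 72 h, and the 10 genes at 6368333 to 6382123 from 72 h (0.43, SE 0.08) to 144 h (1.17, SE 0.04) and 192 h (1.10, SE 0.14).

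The order of the samples on the component that follows time raised the hypothesis that the time course of BC04 runs ahead of that of BC-101-4. On that component BC04 lay ahead at 144 h, at 36.5 against 10.2. The hypothesis was tested on the axis from 48 h to 192 h of the mean of both strains, over 1258 genes that moved at least 2-fold along it. BC04 lay farther along by 0.16 of the way at 72 h, by 0.17 at 96 h and by 0.0744 at 144 h. This axis replaced that of BC-101-4 alone after the latter's values were seen, and the answer depended on it: on that of BC-101-4 alone the difference at 144 h was -0.183, and on that of BC04 alone it was 0.265. BC04 correlated best with the same time of BC-101-4 at 18, 48, 72, 96 and 192 h, and with 192 h at 144 h. Whether the time course of BC04 runs ahead stays open.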
